A study of Mus musculus with 8 samples.

How the data were processed

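Total RNA was extracted with Tri-reagent and cleaned on RNeasy columns, labelled with biotin and hybridised to Affymetrix whole-genome mouse expression arrays, per the labels' protocols. The groups were read from the sample titles: 4 samples of SThdh7/7 and 4 of SThdh111/111. The deposited table gives 1 intensity per probe set and array, on a linear scale. GCRMA is the only tool that the submitters' processing notes name, without a version. The deposited intensity values do not have its form: the mean over probe sets, with 2% trimmed from each end, was 500.0 on all 8 arrays, the arrays shared no quantiles, and values ran below 1 with no common floor. This is the form of Affymetrix MAS5 or GCOS signals, so the tool behind the values is not settled. Such signals are noisy for dim probe sets, which makes log2 differences there imprecise. Detection calls were not used here. The design had been written for log2 values, and allowed for taking log2 of linear ones, which was done; the dim probe set filter had been set with the floor of GCRMA in mind.

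The 64 control probe sets were left out. Probe sets with a log2 intensity of at least 4 on at least 4 of the 8 arrays were kept, 41409 of 45037. Probe sets were named through the platform's gene annotation, with symbols updated by Entrez gene number to the table of assembly GRCm38.p6: 34945 had 1 gene, 932 several and 9160 none, and only the first kind was named. That table gave chromosomes and the order of genes, and no coordinates are given. For each gene the probe set with the highest mean over all arrays was used. Of 826 listed symbols 740 had a probe set named for them alone and 722 were kept.

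Differences (SThdh111/111 minus SThdh7/7) were tested on log2 values of all 8 arrays with lmFit and eBayes with an intensity trend in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and calls at an adjusted p under 0.05. Gene lists and chromosomes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists or the 21 chromosomes, and again for lists with an estimated correlation. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took Htt, Drd2, Penk, Bdnf, Ppargc1a, Crebbp and Actb, the 10 largest fitted rises and 10 largest fitted falls among called genes whose groups did not overlap and whose higher mean was at least 6, the 2 called members of each list with the lowest adjusted p in each direction, and the sex-linked list.

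A floor was chosen after the data were seen: the 95th percentile of 27 bacterial control probe sets, taken at the highest of the 8 arrays, an intensity of 129.8 (log2 7.02), which was on an SThdh7/7 array. The same percentile was lower on every SThdh111/111 array, and 1 floor was used for all. Where every array of 1 line lay below it, the difference is given as "at least N-fold", the mean of the brighter line against the floor. Where some arrays of 1 line lay below it, their values were set to it and the difference is given as "at least" or "or more" on the log2 scale, with the number of arrays above it. No fold is given where both lines lay below it or where the brighter mean was under it.

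The fit was tested on simulated data made from these 41409 probe sets with 4 arrays per group. It recovered 30% of 100 probe sets changed 2-fold and 45% of 100 changed 4-fold, 75.7% and 93.9% of the bright ones, with 2 false calls, and made 0 calls with no change. Only those probe sets were changed, while 22.4% of the kept ones were called in the data. The adjustment was therefore stricter in the simulation, and its rates need not hold for the real fit. A probe set that was not called is still taken as weak evidence of no change unless bright.

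Alternatives fixed before the data were examined were no filter, a filter at a log2 of 6, quantile normalization, centring of arrays on their medians, no intensity trend, array weights, leaving out probe sets whose names end in _x_at, _s_at or _a_at, the sample number as a block, leaving out each sample, and the mean over a gene's probe sets. Chosen after seeing the data were a filter at a log2 of 8, leaving out SThdh7/7 samples 1 and 2, and a term for these samples. Figures were drawn with matplotlib.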

Results

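Total RNA from 2 mouse cell lines, SThdh7/7 and SThdh111/111, was hybridised to Affymetrix whole-genome mouse expression arrays, with 4 samples of each line and 8 arrays in all. Lines of these names are conditionally immortalised striatal cells from embryos of Huntingtin knock-in mice. The number in the name stands for the length of the polyglutamine stretch in both Htt alleles, and the longer stretch models Huntington's disease. The series title concerns genes with reduced expression and the acetylation of their histones, so the comparison asks which transcripts are lower, and which higher, in SThdh111/111. Each group is a single line. Genotype and other differences between the lines could therefore not be separated, and nothing in the labels says that the samples came from separate cultures, so p-values measure only the spread between these samples.

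The arrays carried 45037 probe sets besides 64 controls, and the number of arrays limits the precision. Across all probe sets, arrays correlated at 0.906 to 0.927 within SThdh7/7, at 0.922 to 0.924 within SThdh111/111 and at 0.866 to 0.885 between the lines. SThdh7/7 samples 1 and 2 stood apart from the other 6 arrays. Their median intensities were 173.9 and 174.0, against 136.2 to 147.0 on the others. Their hybridisation controls, bacterial and phage transcripts added at hybridisation, averaged 11.64 and 11.49 on the log2 scale, against 11.99 to 12.28. The bacterial control probe sets that set the floor differed by line. Their 95th percentile was 98.6 to 129.8 on the SThdh7/7 arrays and 72.0 to 77.5 on the SThdh111/111 arrays. Whether this is a difference in background, which would bear on dim probe sets, is not settled. The median intensities of SThdh7/7 samples 3 and 4, 137.7 and 139.7, lay within the SThdh111/111 range of 136.2 to 147.0. The set of samples 1 and 2 of arrays held SThdh7/7 samples only, so it gave no value of its own for the comparison. Probe set counts, gene lists, chromosomes and named genes were also computed without it.

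**Figure D1:**
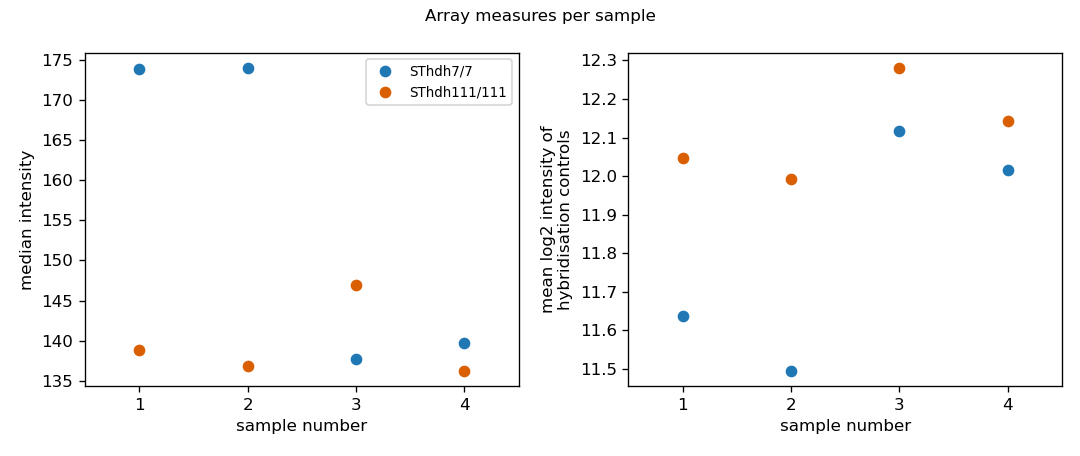
Median intensity of all probe sets (left) and mean log2 intensity of the hybridisation controls (right) on each of the 8 arrays, against the sample number, with 1 point per array. SThdh7/7 samples 1 and 2 had medians of 173.9 and 174.0 and control means of 11.64 and 11.49, apart from the other 6 arrays.

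Htt, the gene whose alleles name the lines, was measured at 9.13 ± 0.18 (log2 intensity, SD, n = 4) in SThdh7/7 and at 8.71 ± 0.30 in SThdh111/111. The 4 arrays of one line did not overlap with the 4 of the other, but the difference of -0.42 ± 0.16 (SE) did not pass the threshold (adjusted p = 0.084). It was -0.27 without SThdh111/111 sample 4, which measured 8.26 against 8.81 to 8.90 on the other 3, and -0.27 without SThdh7/7 samples 1 and 2. It passed when dim probe sets were left out at a log2 of 8, where fewer probe sets were tested (adjusted p = 0.046). Of the other 3 Htt probe sets, 1 fell, by 1.09 on the log2 scale (adjusted p = 0.024). The remaining pair differed by -0.32 and 0.20, with adjusted p of 0.51 and 0.81.

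The lines differed at 9288 of the 41409 probe sets kept (22.4%), 4088 higher and 5200 lower in SThdh111/111. Named genes numbered 17380 after 1 probe set was taken for each, and 2276 of them rose and 2762 fell. Among the called probe sets 3600 differed at least 2-fold, 1633 higher and 1967 lower, and 381 rose and 218 fell at least 8-fold. The share of called probe sets that were lower was 56.0% (95% exact binomial interval 55.0% to 57.0%, which treats probe sets as independent). That share rested on the scaling of the arrays. The median difference over all kept probe sets was -0.12, and 0.03 after each array was centred on its median, where 40.2% of 7319 calls were lower. Differences below are as deposited and can be read against the median of -0.12. Without SThdh7/7 samples 1 and 2 the test called 8431 probe sets, 52.2% of them lower.

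The 10 genes taken for the largest fitted rises were below the floor on most or all SThdh7/7 arrays. They are given as lower bounds against that floor, and the bounds do not show that these rises were the largest. Those of Abi3bp, Arsj, Pawr, Serpina3n and Rspo2 are smaller than the rise of Ifit1, given below, which was bright in both lines. Decorin (Dcn), a proteoglycan of the extracellular matrix, was at 14.36 ± 0.06 (log2 intensity, SD, n = 4) in SThdh111/111 and at least 162-fold higher there (adjusted p = 7.8e-15). The ribonuclease gene Rnase4 was at least 158-fold higher, the platelet chemokine gene Ppbp at least 146-fold and the lysosomal protease gene Ctsz at least 100-fold. Rspo2, which encodes a Wnt signal enhancer, rose at least 52.5-fold, and the protease inhibitor gene Serpina3n at least 51.1-fold. The bounds were at least 15.6-fold for Abi3bp, 13.7-fold for Arsj and 11.03-fold for Pawr. Dcn, Rspo2 and Pawr each had 1 other kept probe set, called in neither direction. The other kept probe sets of Ctsz (2) and Abi3bp (1) were called higher too. The interferon-inducible gene Ifi27l2a was above the floor on 1 of 4 SThdh7/7 arrays and rose by at least 6.78 on the log2 scale, with the other 3 set to the floor.

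The 10 genes taken for the largest fitted falls were below the floor on all SThdh111/111 arrays, and their rank is open in the same way. The water channel gene Aqp5 was at 12.99 ± 0.05 (log2 intensity, SD, n = 4) in SThdh7/7 and at least 62.8-fold lower in SThdh111/111 (adjusted p = 5.4e-08). Crabp1, which encodes a retinoic acid binding protein, was at least 29.2-fold lower, the POU factor gene Pou3f3 at least 24.95-fold, Bex1 at least 24.3-fold and the LIM homeobox gene Lhx2 at least 18.1-fold. Cardiac troponin T (Tnnt2) was at least 13.7-fold lower, Megf10 at least 11.2-fold and the neuronal secreted glycoprotein gene Olfm1 at least 10.4-fold. For Khdrbs3 and Tph2, the enzyme of neuronal serotonin synthesis, the bounds were 2.59-fold and 1.95-fold, because both were dimmer in SThdh7/7, so their place here rests on values below the floor. Every one of these 20 genes separated the 4 arrays of one line from the 4 of the other, which the rule for naming them required.

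Of 29 gene lists, 9 stood apart from other genes by camera at an adjusted p under 0.05, 7 higher and 2 lower in SThdh111/111. With an estimated correlation 3 of them held: cell cycle and DNA replication, interferon response and antigen presentation, and imprinted genes. Among all 35 splits of the 8 arrays into 4 and 4, 8 gave 9 or more called lists, the real split included. The other 7 set 3 arrays of one line and 1 of the other against the rest, and splits with 2 arrays of each line in both parts called at most 5. With an estimated correlation the real split called 3 lists and each of the other 34 called 0. Those 34 splits mix the lines, which widens the spread within their parts, so their 0 calls do not measure chance. Counts adjusted over the list alone were the same as those over all probe sets except where both are given. Of the genes named here, Tnnt2, Acta2, Hoxa10, Plagl1, Sqstm1, Meis2, Ncam1, Cenpa, Hip1r and Xist lost their calls when probe sets that can match several transcripts were left out, which put another probe set in their place.

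**Figure D2:**
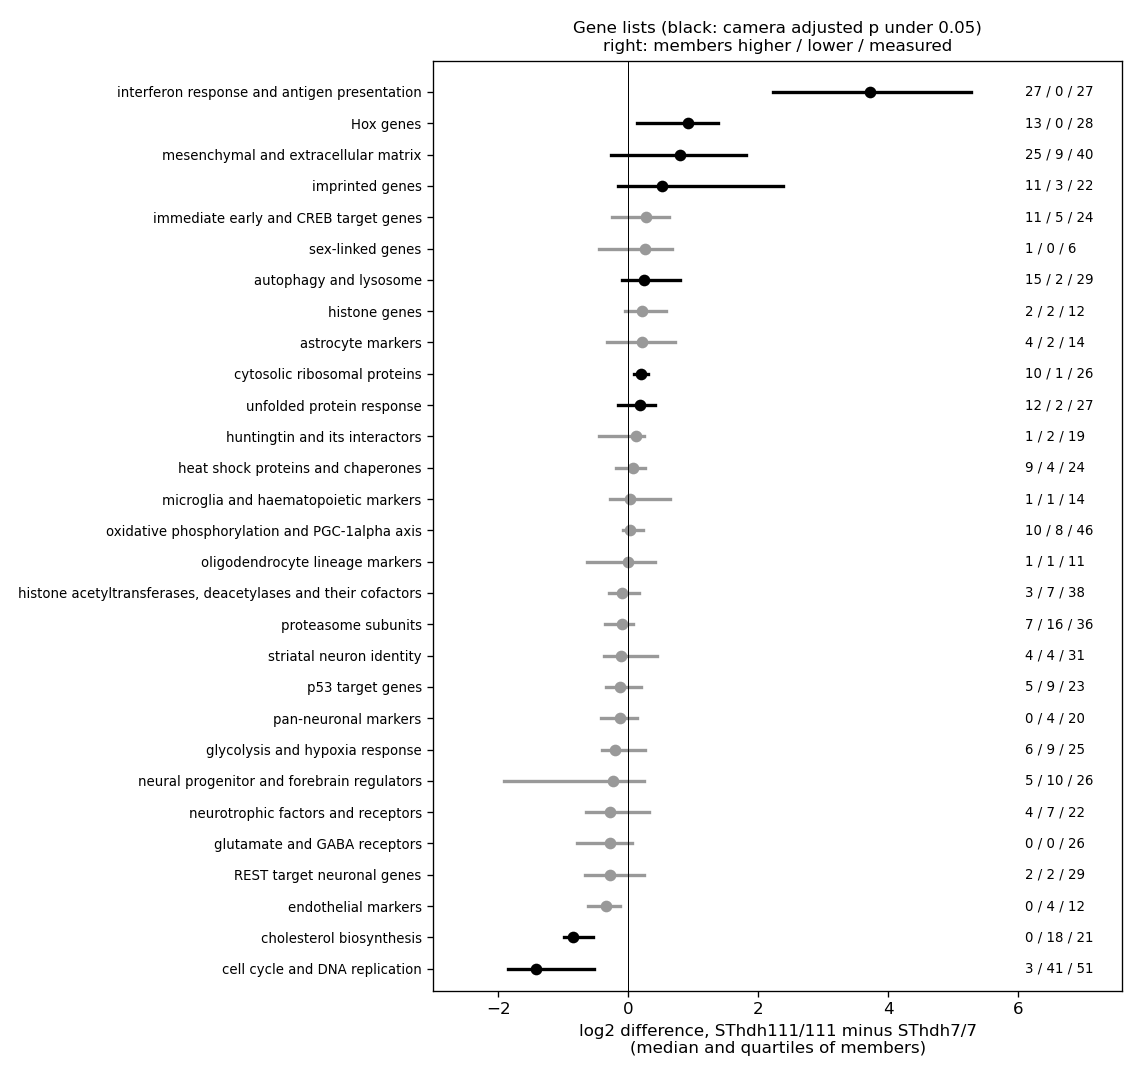
Median (point) and quartiles (bar) of the log2 difference, SThdh111/111 minus SThdh7/7, over the measured members of each of 29 gene lists. Black marks lists past the camera threshold, and the figures at the right give members higher, lower and measured. The interferon list has a median of 3.72 and the cell cycle list a median of -1.41. The ribosomal list, black here, has a median of -0.04 after quantile normalization.

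Genes of the interferon response and of antigen presentation were higher in SThdh111/111 without exception. All 27 measured members rose, with a median difference of 3.72 (camera adjusted p = 9.4e-40; adjusted p = 0.0013 with an estimated correlation). Ifit1 and Ifit3, interferon-induced RNA-binding proteins of the antiviral response, were already bright in SThdh7/7 at 9.10 ± 0.08 and 10.13 ± 0.07 (log2 intensity, SD, n = 4). They reached 14.83 ± 0.07 and 15.00 ± 0.06 in SThdh111/111, rises of 5.73 ± 0.07 and 4.87 ± 0.06 (SE; adjusted p = 7.8e-15 and 1.1e-14). Psmb8 and Psmb9, subunits of the immunoproteasome, were each above the floor on 1 of 4 SThdh7/7 arrays and rose by at least 4.18 and 3.87 on the log2 scale. Of the microglia and haematopoietic markers, measured beside them, 1 of 14 rose (Csf1r, by 0.49, not called with the mean of its probe sets) and 1 fell (Cd68, by 1.75 on the log2 scale), and the list was not called (camera adjusted p = 0.99).

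Cell cycle and DNA replication genes were lower in SThdh111/111. Of 51 measured members 41 fell and 3 rose, 42 and 3 adjusted over the list alone (median difference -1.41; camera adjusted p = 5.1e-19; adjusted p = 0.0011 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 1.86 on the log2 scale, from 12.45 ± 0.02 to 10.59 ± 0.09 (SD, n = 4; adjusted p = 1.2e-10). Cyclin D1 (Ccnd1) fell by 1.73 on the log2 scale, from 13.56 ± 0.06 to 11.83 ± 0.11. The inhibitor gene Cdkn2c rose by 0.74 ± 0.07 (SE). Cyclin D3 (Ccnd3) rose by 0.55 ± 0.08 (SE) at its brightest probe set, but its mean over all probe sets was -0.36.

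Cholesterol biosynthesis genes were also lower, with 18 of 21 falling and 0 rising (median difference -0.86; camera adjusted p = 4.7e-11; adjusted p = 0.072 with an estimated correlation). Fdps, the farnesyl diphosphate synthase, fell by 1.25 on the log2 scale (adjusted p = 2.9e-08) at its brightest probe set, with a mean over all its probe sets of -0.07, and Ebp, a sterol isomerase, by 1.06 on the log2 scale (adjusted p = 1.7e-08).

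Genes of the extracellular matrix and mesenchymal cells moved both ways, 25 of 40 rising and 9 falling (median difference 0.80; camera adjusted p = 1.3e-08; adjusted p = 0.072 with an estimated correlation). Besides decorin, the collagen gene Col1a2 rose by 4.34 ± 0.07 (SE). Smooth muscle actin (Acta2) and the collagen gene Col5a1 fell by 1.76 and 1.19 on the log2 scale. Among Hox genes, which specify position along the body axis, 13 of 28 rose and 0 fell, 14 and 0 adjusted over the list alone (median 0.92; camera adjusted p = 1.9e-04; adjusted p = 0.072 with an estimated correlation). Hoxa11 rose by 2.47 ± 0.19 (SE), and Hoxa10, above the floor on 1 of 4 SThdh7/7 arrays, by at least 4.71 on the log2 scale. Of those 28 Hox genes 8 lay below the floor in both lines, and with genes below the floor set to it the median was 0.33.

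Imprinted genes, expressed from a single parental allele, rose in 11 of 22 cases and fell in 3, 11 and 4 adjusted over the list alone (median difference 0.52; camera adjusted p = 5.1e-05; adjusted p = 0.028 with an estimated correlation). The size of that median depended on the setting: it was 0.97 without SThdh7/7 samples 1 and 2, 1.47 over the 14 members left by a filter at a log2 of 8, and 0.34 with values below the floor set to it. Mest went from 8.67 ± 0.08 to 13.67 ± 0.05 (log2 intensity, SD, n = 4; adjusted p = 1.9e-14), and the zinc finger gene Plagl1, above the floor on 1 of 4 SThdh7/7 arrays, rose by at least 4.88 on the log2 scale. Ndn fell by 0.81 on the log2 scale. Impact was lower (difference -0.38), a call lost after centring, where 11 members were higher and 1 lower, and with the mean of its probe sets.

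The remaining called lists moved less. Of 29 autophagy and lysosome genes 15 rose and 2 fell, 16 and 2 adjusted over the list alone (median 0.25; camera adjusted p = 1.1e-05; adjusted p = 0.072 with an estimated correlation). They included Gabarapl1, an autophagosome protein, up from 11.72 ± 0.08 to 13.22 ± 0.07 (log2 intensity, SD, n = 4), and the lysosomal cholesterol carrier gene Npc2, up by 1.01 ± 0.06 (SE), while Sqstm1 and Atg7 were lower (differences -0.38 and -0.78). Both of these calls were lost after centring, where 14 members were higher and 0 lower, and Atg7 stood at -0.52 without SThdh111/111 sample 3. Of 27 unfolded protein response genes 12 rose and 2 fell, 12 and 4 adjusted over the list alone (median 0.18; camera adjusted p = 0.019; adjusted p = 0.27 with an estimated correlation). Ddit3 rose by 0.98 ± 0.07 (SE) and Manf by 0.58 ± 0.07 (SE), while Ero1a fell by 0.66 on the log2 scale and Chac1 was lower (difference -0.42), a call lost after centring. The call of the list was lost without SThdh7/7 sample 1 (adjusted p = 0.054) and without samples 1 and 2 (median 0.10; adjusted p = 0.14). Of 26 cytosolic ribosomal protein genes 10 rose and 1 fell, 13 and 1 adjusted over the list alone (median 0.19; camera adjusted p = 0.0011; adjusted p = 0.55 with an estimated correlation). Rps19 rose by 0.51 ± 0.06 (SE). Rps25 was lower (difference -0.40; adjusted p = 0.041), but the lines overlapped and the call was lost in 7 of 8 fits with 1 sample left out. After quantile normalization 3 ribosomal genes were higher and 5 lower, the median was -0.04 and the call was gone (adjusted p = 0.70), and without SThdh7/7 samples 1 and 2 the median was 0.10 (adjusted p = 0.016). After centring of the arrays the medians of these 3 lists were 0.39, 0.33 and 0.34.

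Of 31 striatal identity genes 4 rose and 4 fell (camera adjusted p = 0.99). Proenkephalin (Penk), a peptide precursor of striatal projection neurons, was above the floor on 1 of 4 SThdh7/7 arrays and rose by at least 2.41 on the log2 scale (adjusted p = 2.5e-05), and the signalling regulator gene Rgs4 was at least 1.87-fold higher. The homeobox gene Meis2 and the phosphodiesterase gene Pde1b fell by 1.78 and 1.85 on the log2 scale. The dopamine receptor gene Drd2 lay around the floor, above it on 2 of 4 arrays of each line, at 6.49 ± 1.86 and 6.90 ± 0.81 (log2 intensity, SD, n = 4; adjusted p = 0.77). Of 29 neuronal targets of the repressor REST 2 rose and 2 fell (camera adjusted p = 0.99), among them L1cam, up by 1.48 ± 0.15 (SE), and Bdnf, a neurotrophin gene, which fell by 0.67 on the log2 scale (adjusted p = 4.4e-04). The second Bdnf probe set differed by -0.37 (adjusted p = 0.075). Of 20 pan-neuronal markers 4 fell and 0 rose (camera adjusted p = 0.27). A filter at a log2 of 8 left 5 of them, 4 lower, and the list was then called lower (median -1.76, camera adjusted p = 0.016). That filter asked for 4 of 8 arrays, so a gene bright in SThdh7/7 alone could pass it. The members left can thus be chosen in part by their difference, and the call is not separate evidence of a fall. Dpysl3 and Ncam1, above the floor on 3 and 1 of 4 SThdh111/111 arrays, fell by 4.40 and 2.63 or more on the log2 scale.

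**Figure D3:**
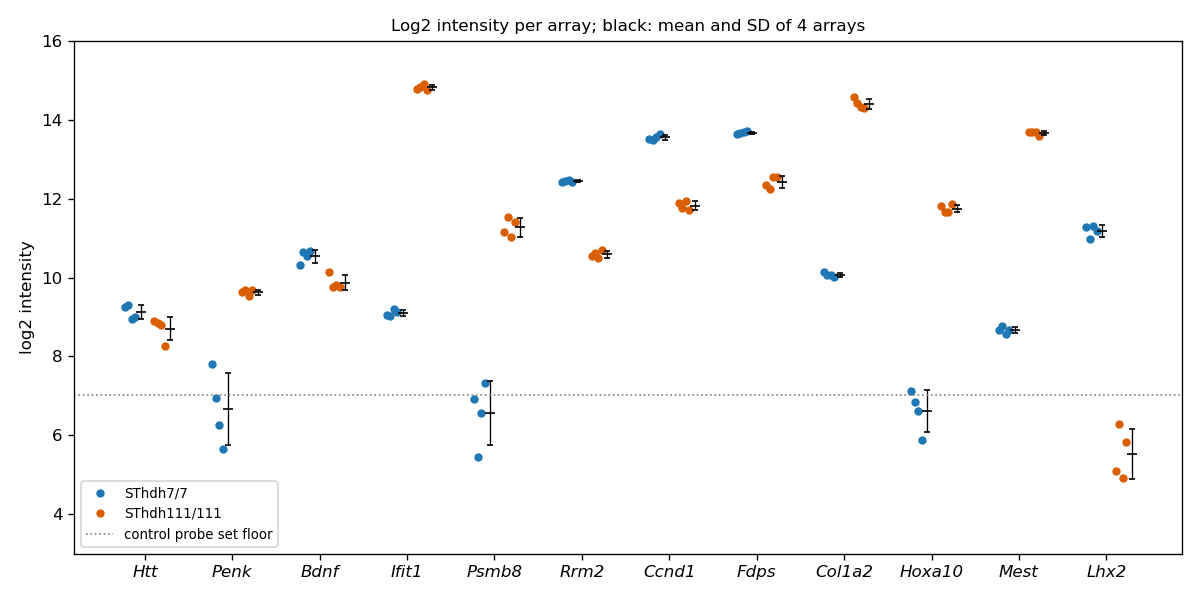
Log2 intensity of 12 genes on each array, with 4 points per line (blue SThdh7/7, orange SThdh111/111), the mean and SD in black, and the control probe set floor of 7.02 as a dotted line. Ifit1, Col1a2, Hoxa10 and Mest lie higher in SThdh111/111 and Rrm2, Ccnd1, Fdps and Lhx2 lower. The SDs of Htt meet, although its points do not overlap between the lines.

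Regulators of neural progenitors and the forebrain moved both ways, 5 of 26 higher and 10 lower (camera adjusted p = 0.17; adjusted p = 0.036 after centring of the arrays). Zic1, a zinc finger gene of the dorsal neural tube, was at least 21.4-fold higher and Id3 rose by 0.88 ± 0.08 (SE), while the Notch target Hes1 fell by 2.12 on the log2 scale and Lhx2 fell as given above. Markers of other cell types were mixed. Of 14 astrocyte markers 4 rose and 2 fell (camera adjusted p = 0.30), with Clu up by 2.12 ± 0.10 (SE) and Cd44 lower (difference -1.25). Of 11 oligodendrocyte lineage markers 1 rose, Pdgfra, and 1 fell, Cnp (camera adjusted p = 0.99), a call lost after centring. Of 12 endothelial markers 4 fell and 0 rose (camera adjusted p = 0.25), but 1 was lower after centring, where the call of Ets1 (difference -0.62) was among those lost.

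The series title concerns histone acetylation, and its enzymes changed singly. Of 38 acetyltransferases, deacetylases and their cofactors 3 rose and 7 fell (camera adjusted p = 0.73), but 5 were higher and 4 lower after centring of the arrays. Ep300, an acetyltransferase, rose by 0.72 ± 0.10 (SE), and Sirt5 by 0.56 ± 0.10 (SE). The acetyltransferase gene Hat1 fell by 0.73 on the log2 scale, and the deacetylase gene Hdac9 was at least 1.94-fold lower. Crebbp, a paralogue of Ep300, differed by 0.04 ± 0.10 (SE; adjusted p = 0.85). Of 12 histone genes 2 rose and 2 fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.17), and 5 were higher and 1 lower after centring. The centromeric histone gene Cenpa fell by 2.17 on the log2 scale. H1f2 rose by 2.10 ± 0.10 (SE) at its brightest probe set, but differed by -0.14 when probe sets that can match several transcripts were left out.

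Ppargc1a, a coactivator of mitochondrial genes, rose by 0.54 ± 0.14 (SE; adjusted p = 0.013), a call lost without SThdh7/7 samples 1 and 2 (difference 0.34; adjusted p = 0.11) and without an intensity trend (adjusted p = 0.072). Of the 4 other kept probe sets of Ppargc1a 3 were called higher too and 0 lower. Of 46 genes of oxidative phosphorylation 10 rose and 8 fell, 11 and 8 adjusted over the list alone (camera adjusted p = 0.25). The balance turned with the scaling, with 7 higher and 15 lower after quantile normalization (median -0.08) and 8 higher and 1 lower after centring (median 0.17). Of 25 genes of glycolysis and hypoxia 6 rose and 9 fell, 8 and 10 adjusted over the list alone (camera adjusted p = 0.79), but 7 were higher and 3 lower after centring, with Hif1a up by 1.58 ± 0.07 (SE) and Hk1 lower (difference -0.83). Of 24 heat shock proteins and chaperones 9 rose and 4 fell, 9 and 6 adjusted over the list alone (camera adjusted p = 0.25), but 5 were higher and 6 lower after quantile normalization, with Bag3, above the floor on 1 of 4 SThdh7/7 arrays, up by at least 2.63 on the log2 scale. Of 36 proteasome subunits 7 rose and 16 fell (camera adjusted p = 0.32), and the immunoproteasome genes Psmb8 and Psmb9 made the list's mean, 0.18, differ in sign from its median, -0.10. After quantile normalization 20 of the 36 were lower and the list was called (median -0.24; adjusted p = 0.0089), while after centring 6 were higher and 2 lower (median 0.05; adjusted p = 0.91). Psmd14 fell by 0.65 on the log2 scale. Psmd2 was lower at its brightest probe set (difference -0.57), but the mean over its probe sets was -0.13 and not called.

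Signalling lists were mixed as well. Of 23 p53 targets 5 rose and 9 fell (camera adjusted p = 0.38; adjusted p = 0.042 after quantile normalization), but 5 were higher and 4 lower after centring, with Btg2 up by 1.08 ± 0.12 (SE) and Pmaip1 lower (difference -2.14). Of 24 immediate early and CREB target genes 11 rose and 5 fell, 12 and 5 adjusted over the list alone (camera adjusted p = 0.097; adjusted p = 0.031 without SThdh111/111 sample 3). Fos rose by 1.47 ± 0.12 (SE), and Ptgs2, the inducible cyclooxygenase, fell by 2.83 on the log2 scale. Of 22 neurotrophic factors and receptors 4 rose and 7 fell (camera adjusted p = 0.77). The leukaemia inhibitory factor receptor gene Lifr was at least 17.1-fold higher, Artn at least 6.24-fold lower, and Igf1, above the floor on 2 of 4 SThdh111/111 arrays, fell by 2.85 or more on the log2 scale. Of 26 glutamate and GABA receptor genes 0 rose and 0 fell (camera adjusted p = 0.81), and 8 of them were below the floor in both lines. Of 19 genes for huntingtin and its interactors 1 rose, Hap1, by 0.76 ± 0.11 (SE), and 2 fell, Rasa1 and Hip1r (camera adjusted p = 0.81), while after centring 3 were higher and 1 lower and the call of Hip1r was lost. Beta-actin (Actb) differed by -0.05 ± 0.07 (SE; adjusted p = 0.71). The lists of striatal identity, immediate early genes, glycolysis and huntingtin and its interactors also had means and medians of opposite sign.

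Xist, the RNA that silences an X chromosome in female cells, was bright in both lines, at 11.75 ± 0.30 and 12.43 ± 0.14 (log2 intensity, SD, n = 4), and rose by 0.68 ± 0.12 (SE). The antisense gene Tsix and the Y-linked genes Eif2s3y and Kdm5d were below the floor on all arrays, while Uty and Usp9y were below it on all arrays of 1 line and close to it in the other. Of 6 measured sex-linked genes 1 rose and 0 fell (camera adjusted p = 0.56). No chromosome stood apart from the rest: camera called 0 of 21, and 3 had an unadjusted p under 0.05. When dim probe sets were left out at a log2 of 8, 2 were called, chromosomes 14 and 16, with medians of -0.20 and -0.21 (adjusted p = 0.036 for both).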

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

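Chosen only after the result was seen were the tests of blood cell markers and of background or scaling in SThdh7/7 samples 1 and 2. Leaving these samples out was an alternative added after the data were seen. The remaining tests of explanations in this part were chosen after the patterns were seen, with bounds written before their own results. In 14 of 252 groups of 4 arrays that were examined for a single array far from the others, 1 array stood apart; chance gives about 5% of groups. In SThdh7/7, sample 1 was low for Pawr (log2 intensity 1.21), Tph2 (7.74) and Manf (12.36), sample 4 was low for Rspo2 (3.75) and Psmd2 (12.87), and sample 3 was high for Perp (13.20). In SThdh111/111, sample 4 was low for Htt (8.26, against 8.81 to 8.90) and Mest (13.59) and high for Lifr (11.15) and Usp9y (6.70), sample 1 was high for Bdnf (10.15) and low for Pou3f3 (4.35), and sample 3 was low for Pdgfra (8.40). The log2 ratio of the 3' to the 5' Gapdh control probe sets was high in SThdh111/111 sample 3, at -0.466.

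All 27 interferon and antigen presentation genes rose in SThdh111/111, by a median of 3.72. The upper quartile of the differences of 14 markers of microglia and other blood cells was 0.65. This lay below the lower quartile of 2.23 of the interferon list. The bound replaced an earlier one, which also asked for most markers below the floor and was not met (6 of 14 were). Markers that dim cannot be read. The values speak only against a rise of the readable markers as large as that of the interferon genes, and blood cells are not excluded. The tables argue against the set of arrays of SThdh7/7 samples 1 and 2, as the median without them was 3.87 and all 27 stayed called. Of 10 interferon ligand probe sets 0 were called higher and above the floor on all SThdh111/111 arrays, which by the bound written before would exclude interferon expressed by the cells; 3 were above it on all of these arrays and not called, Ifnb1 with a difference of 0.17 and Ifna1 and Ifnz, above it on 1 and 3 of 4 SThdh7/7 arrays, with at least 0.38 and 0.72 (adjusted p = 0.77, 0.21 and 0.14). That bound was set aside after the result was seen, because the other 7 lay below the floor on at least 1 of these arrays, where absence cannot be read (Ifna4 was called higher with both means under the floor), and a missed threshold does not show that the 3 were equal, so this explanation stays open, as do genotype and line, which were not tested.

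Cell cycle and cholesterol genes were lower in SThdh111/111. The highest of the 4 medians of these lists after centring and quantile normalization was -0.71. Centring moves the difference of every gene by the same amount, so its medians follow from the shift between the arrays. Quantile normalization, which is not bound in this way, left medians of -1.36 for cell cycle and -0.85 for cholesterol. These values argue against scaling of the arrays as the whole of the difference. Leaving out SThdh7/7 samples 1 and 2 left the higher of the 2 medians at -0.82. Growth rate, density at harvest, genotype and line stay open as untested explanations.

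SThdh7/7 samples 1 and 2 differed from samples 3 and 4 by a median of 0.43 in the dimmest 25% of probe sets and of -0.04 in the brightest 25%. Background or scaling of the arrays is a candidate explanation that has this form, in a test chosen after the difference was seen. A limma fit of these 2 against 2 arrays called 2 probe sets, and no biological explanation was tested, as the labels give none.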

How the results depend on the processing

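The filter at a log2 of 8, leaving out SThdh7/7 samples 1 and 2, and the term for these samples were chosen after the results were seen. The count of 9288 called probe sets ran from 8115 to 8754 with 1 sample left out and was 8827 under the log2 8 filter, but 6132 without probe sets whose names end in _x_at, _s_at or _a_at, where 32876 were tested. The count of at least 2-fold differences fell to 2365 under the log2 8 filter, which tested 17603. The percentage of calls that were lower was 53.6 after quantile normalization, 40.2 after centring, 57.2 without the _x_at, _s_at and _a_at probe sets, 54.2 under the log2 8 filter, 52.2 without SThdh7/7 samples 1 and 2, 53.9 with the term for them, and 53.9 to 56.9 with 1 sample left out; the cause was not tested. Same-numbered samples did not deviate together over the kept probe sets (r of 0.009, -0.008, -0.014 and 0.009). No pairing by number was seen, but many of these probe sets were dim, so a pairing is not excluded. With the sample number as a replicate block 8828 probe sets were called.

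With an estimated correlation 3 lists were called, and adjusted p was 0.0724 for extracellular matrix, cholesterol, autophagy and Hox genes, 0.269 for the unfolded protein response and 0.553 for ribosomal proteins. The unfolded protein response had adjusted p of 0.230 after quantile normalization, 0.347 without the _x_at, _s_at and _a_at probe sets, 0.0949 under the log2 8 filter, 0.142 without SThdh7/7 samples 1 and 2, 0.121 with the term, and 0.00737 to 0.0539 with 1 sample left out. Ribosomal proteins turned lower after quantile normalization (adjusted p = 0.703), and had 0.944 without the _x_at, _s_at and _a_at probe sets. Lists called only elsewhere were proteasome (0.0089) and p53 targets (0.042) after quantile normalization, progenitor regulators (0.036) after centring, pan-neuronal markers (0.016) under the log2 8 filter, and immediate early genes (0.0306) without SThdh111/111 sample 3. The causes were not tested. Under the log2 8 filter 2 chromosomes were called.

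Htt stood at -1.09 without the _x_at, _s_at and _a_at probe sets, which left another probe set, and at -0.42 with adjusted p of 0.046 under the log2 8 filter. Without those probe sets Aldh1l1 turned to 1.16, H1f2 to -0.14 and Rps18 to -1.51, and with the mean of a gene's probe sets Ccnd3 turned to -0.36 and Rps18 to -0.39, none of them called. Without those probe sets the calls of Tnnt2, Meis2, Ncam1, Acta2, Cenpa, Sqstm1, Hoxa10, Plagl1, Xist, Fgfr2, Flt1, H2ax and Hip1r were lost too, with the mean those of Fdps, Csf1r, Psmd2, Stmn2, Aldh1l1 and Impact, and after centring those of Chac1, Sqstm1, Atg7, Impact, Rps25, Ets1, Cnp, Cycs, H2ax and Hip1r. Lost without an intensity trend were Ppargc1a, Cnp, H2ax, Sqstm1, Atg7, Impact and Rps25, and without SThdh7/7 samples 1 and 2 Ppargc1a, Stmn2, Cnp, H2ax, Atg7 and Rps25, and the same except Atg7 with the term. The calls lost under other settings, or with 1 sample left out, were of Rps25, H2ax and Stmn2. Of 2392 values of 121 named genes over 20 alternatives, 2315 kept direction and side of the threshold, 70 lost the call, 2 gained it and 5 reversed. Signal over background limits the dim end: 24.7% of kept probe sets lay below the floor in both lines.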

Other observations

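The tests of gene families in this part were chosen after the results were seen, and the named members were chosen after their values were seen. Tests of neighbouring genes, of genes near Htt and of other splits were chosen before their own results. They were not in the plan fixed before the data were examined. Genes were grouped by the letters that open their symbols, which gave 243 families of at least 10 measured genes. Camera called 11 of them at an adjusted p under 0.05, and 0 with an estimated correlation. Among chemokines of the Cxcl family 7 of 13 rose and 0 fell (adjusted p = 5.4e-04), with Cxcl15 at least 70.4-fold and Cxcl11 at least 8.41-fold higher and Cxcl1 up by 3.15. In the Parp family 6 of 11 rose and 2 fell (adjusted p = 0.026): the interferon-inducible members Parp9 and Parp12 rose by 2.62 and 2.59 and Parp14, above the floor on 1 of 4 SThdh7/7 arrays, by at least 3.69 on the log2 scale, while the DNA repair enzyme Parp1 fell by 0.75 on the log2 scale. The Ifi family, with 9 of 13 rising (adjusted p = 6.0e-08), and the Hoxa family, with 6 of 10 (adjusted p = 0.0024), were also called higher; 8 of the Hoxa genes are in the Hox list of the report, while the Ifi and Cxcl families each share 1 gene with its interferon list. Families named S and H, which mix unrelated genes, were called higher too.

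The remaining 5 families were called lower, and 3 of them share genes with lists of the report, so they are not independent of these: 7 Mcm and 2 Kif genes are in the cell cycle list and 11 Psmd genes in the proteasome list. Of 10 Mcm genes, most of which encode subunits of the replicative helicase, 8 fell and 0 rose (adjusted p = 4.3e-05). Of 19 Nup genes of the nuclear pore 8 fell and 0 rose (adjusted p = 0.024), as did 8 of 16 Rad genes, many of them of DNA repair (adjusted p = 0.036). Among Kif genes, which encode kinesin motors, 14 of 34 fell and 2 rose (adjusted p = 0.022), with Kif18b and Kif22 at differences of -1.64 and -1.85. Kif26b, above the floor on 1 of 4 SThdh111/111 arrays, fell by 3.43 or more on the log2 scale, Kif5c, above it on 2 of 4, fell by 2.46 or more on the log2 scale, and Kif16b rose by 1.15. Among Psmd genes of the proteasome's regulatory particle 9 of 14 fell and 1 rose (adjusted p = 0.014). Each of the 11 medians kept its sign after quantile normalization. They also kept it after centring, but centring moves every gene by the same amount, too little here to turn any of them.

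The real split called 9288 probe sets and the highest of the other 34 splits of the 8 arrays called 0. So 1 of 35 splits reached it, the smallest share possible, which met the bound written before. Every other split mixes the lines, so a clear line difference widens the spread within its parts, which can by itself leave 0 calls. This count therefore does not measure chance, and any difference between the 2 groups of samples could give it. For the number of lists at the preset correlation chance is not excluded. The real split called 9 and the highest other 13, and 8 of 35 reached 9, the other 7 of them uneven. With an estimated correlation the real split called 3 lists and each of the other 34 called 0. There too the mixed lines widen the spread, so these 0 calls are no evidence against chance. The splits differ in how much of the line difference they hold. The 16 uneven splits, with 3 arrays of one line and 1 of the other in each part, called 5 to 13 lists, while the 18 even ones called 0 to 5, with 12 calling 0. In the even splits the lowest adjusted p of the interferon list was 0.54, against 9.4e-40 in the real split. Even splits balance the lines, so a line difference cancels in them and this contrast follows from the design. This comparison by kind of split was made after the counts were seen.

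Of 9292 windows of 25 neighbouring bright genes, 7 had an absolute median past the 95th percentile of the largest in 200 permuted gene orders (0.55). They lay in 3 stretches. On chromosome 3, from Pex5l to Sclt1, 16 of 28 genes fell and 2 rose. On chromosome 14, ending at Exoc5, 17 of 26 fell and 1 rose, and on chromosome 8, beginning at Trappc2l, 15 of 26 rose and 1 fell. Of all bright genes in this test 46.2% were called, and the 3 stretches were picked for their extreme medians. A regional difference between the lines such as a gain or loss of part of a chromosome may account for these 7 windows, as a hypothesis; shared regulation of neighbours stays open and was not tested. Around Htt, 15 of the 50 nearest measured genes were called, which is 30% against a median of 30% and a 95th percentile of 42% over 16225 windows of that size, so no excess of differences was seen next to the knock-in locus.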
